A study of Homo sapiens with 6 samples.

How the data were processed

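RNA sequencing of MCF-7, an established human breast adenocarcinoma cell line, was analysed in 3 groups of 2 libraries. The groups were untreated cells, cells given 0.3 µM GQC-05 and cells given 20 µM GTC365, both for 72 h. No time is given for the untreated libraries, whose titles name no vehicle. Effects of solvent or culture time therefore cannot be separated here from those of a ligand. Each compound is a ligand of G-quadruplexes (G4), folded structures of guanine-rich DNA, and is known here only by its code name. Per the labels' protocols, RNA was extracted on RNeasy columns and converted to libraries with a stranded total RNA kit that removes ribosomal RNA. Chromatin accessibility sequencing named in the study's design was not analysed here.

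The authors deposited whole-number read counts per gene, not normalised, with a column for each library and genes given as NCBI Gene numbers. Per the submitters' processing notes, the tools were STAR 2.5.3a, featureCounts 1.5.3 and edgeR, on genome build hg38. The strand setting, the treatment of reads that map to several places and the annotation release were not given in the sources used here. Reads of overlapping, antisense or near-identical genes may therefore have been shared between them, and such genes are named as uncertain. Total counts ran from 12387664 to 14064949 per library. The table held 29472 genes, of which 8528 had no read in any library. Symbols and coordinates came from a RefSeq gene table of the same build, which matched 27445 genes (93.1%). The 2027 unmatched numbers stayed in the tests.

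Libraries were placed in groups by their titles. Counts of every pair of libraries were compared by a chi-square statistic over genes, and no pair held identical counts. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Replicate numbers 1 and 2 occur in each group, but no label says that a number marks a batch. They were therefore not used to pair libraries.

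Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), which left 13900 tested genes and removed 15572. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was fitted to all 6 libraries with TMM factors, and all 3 contrasts between groups were taken from that fit. It had 3 residual and 7.63 total degrees of freedom, with a common biological coefficient of variation of 11.1%. P-values were adjusted by Benjamini-Hochberg over the tested genes of each contrast, and a gene was called changed at an adjusted p under 0.05. "Rose" and "fell" are used only of such genes. Fold changes are given as log2 ± SE, the SE being the log2 change divided by the square root of the F statistic. Normalised counts are given in CPM, scaled to the total of the tested genes in each library times its TMM factor, as mean ± SD of the 2 libraries of a group. The CPM of RN7SL1, RN7SL2 and RNAs without a poly(A) tail use each library's full total with no such factor.

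The comparisons, the thresholds, 32 gene lists with 952 members, the rule for naming genes and the alternatives were set before the data were examined, except where a choice is said to be later. Symbols of 938 list members were matched. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes moved 1 way on balance, were alternatives. The count of changed members was also taken with p-values adjusted over the list alone.

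Genes were named by rule. Against untreated cells, these were the 6 largest rises and 6 largest falls among changed genes with a mean of at least 5 CPM, a symbol, and both libraries of a group above both of the other. Between the ligands 5 and 5 were taken. For each list that passed camera, the 3 members with the smallest p in its direction were taken, and for other lists at most 2 changed members. MYC, TERT, KIT, KRAS, BCL2, VEGFA, CDKN1A, ESR1 and CYP1A1 were always included. Where no gene passed, the 3 smallest p-values in each direction were taken.

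Both ligands were compared with the same untreated libraries, so the correlation of their fold changes was set beside 20 simulations. In these, counts of all 6 libraries were redrawn from the untreated means, with no change in any group. Gene span was related to fold change over 12508 tested protein-coding genes in 5 classes of equal size. A planned search for G4 motifs around gene starts was not run, because no genome sequence was used here. In its place, a motif of 4 runs of at least 3 G, with loops of 1 to 7 bases on either strand, was sought in up to 500 bp of the first exon of GENCODE release 29 transcripts. This choice was made after the data were examined.

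The test was first run on simulated data with 200 changed genes drawn at the observed means and library sizes. For GQC-05 against untreated (13730 genes) it recovered 70.1% of 2-fold and 22.4% of 1.5-fold changes. The shares were 85.1% and 22.4% for GTC365 against untreated (13732 genes), and 82.1% and 26.9% for GTC365 against GQC-05 (13751 genes). In the same order, 12, 10 and 10 unchanged genes were also called. A list of 40 genes shifted by a log2 of 0.25 passed camera with the preset correlation in all 3 simulated comparisons, and did not pass with an estimated correlation (adjusted p from 0.155 to 0.256). Its genes were drawn independently of each other.

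Alternatives were other size factors, library size alone, other filters on low counts, DESeq2 1.42.0, limma-voom, fits of only the groups compared, a robust fit, a term for the replicate number, a fit without abundant non-coding RNAs, and fits without each library in turn. In the last, the lone library of a group is assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.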

Results

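Gene counts were measured in 6 RNA-seq libraries of MCF-7 cells, 2 untreated, 2 treated with 0.3 µM GQC-05 and 2 treated with 20 µM GTC365. Total counts were 13685185 and 14064949 in the untreated libraries, 13304918 and 12387664 with GQC-05, and 13428016 and 13450254 with GTC365. The comparisons ask how each treatment, described by the submitters as stabilising G4 structures, altered gene expression. The first principal component carried 57.3% of the variance and placed both GTC365 libraries (32.5 and 44.1) apart from the untreated (-30.8 and -18.7) and GQC-05 libraries (-15.5 and -11.7). The second, with 17.7%, placed replicate 2 below replicate 1 in each group. Differences between libraries exceeded sampling noise for every pair, with a chi-square per degree of freedom of 12.5 between the untreated libraries, 8.92 between those of GQC-05 and 10.3 between those of GTC365. The closest pair was untreated replicate 2 and GQC-05 replicate 2 (3.49), from different groups.

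GTC365 lowered genes of cell division and DNA replication together and raised p53 target genes. Against untreated cells 2629 of 13900 genes changed, 1190 upward and 1439 downward, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 287 rose and 448 fell by at least 2-fold. CDKN1A, which encodes the cell cycle inhibitor p21, rose by a log2 of 2.37 ± 0.20 (SE), from 165 ± 39.3 to 855 ± 162 CPM (SD, n = 2 libraries each). KIF20A, a kinesin of cytokinesis, fell 7.97-fold, from 130 ± 9.74 to 16.3 ± 3.78 CPM. The number of changed genes was 1075 without untreated replicate 1, 1615 without GTC365 replicate 1 and 930 without GTC365 replicate 2. Of these genes, 1051, 1470 and 916 were among the 2629, all in the same direction.

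**Figure D1:**
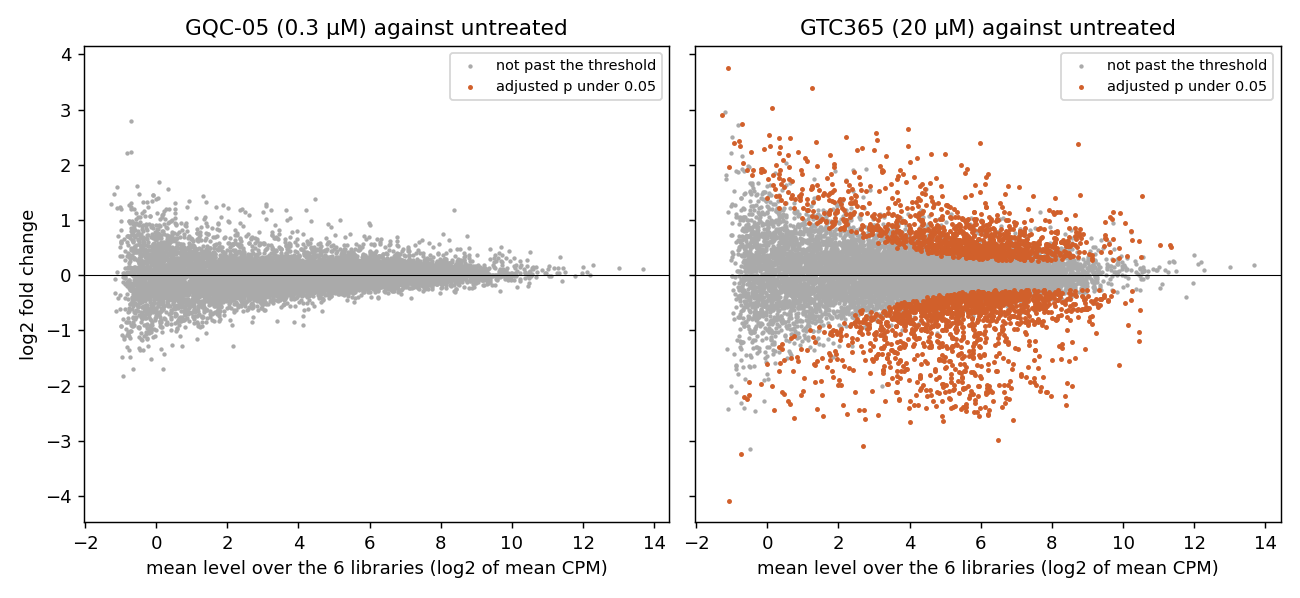
Log2 fold change against mean expression (log2 CPM) for each ligand against untreated, with 1 point per tested gene. Coloured points are genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test. No gene passed for GQC-05 against untreated, against 2629 for GTC365 against untreated.

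The largest rises after GTC365 were in TNFRSF10C (2.65 ± 0.26), a decoy receptor for the death ligand TRAIL, the long non-coding RNA LINC01522 (2.57 ± 0.45), ZNF488 (2.44 ± 0.40), the stress-induced cytokine gene GDF15 (2.39 ± 0.34), CDKN1A and the smooth muscle actin gene ACTA2 (2.34 ± 0.27). CDKN1A (NCBI Gene 1026) lies on chromosome 6 at 36676463 to 36687332 of hg38, and GDF15 (9518) on chromosome 19 at 18386158 to 18389176. Adjusted p-values in edgeR's quasi-likelihood test ran from 3.01e-04 (CDKN1A) to 0.00841 (LINC01522). TNFRSF10C has close paralogs and ACTA2 overlaps an antisense gene, so their counts may hold reads of those genes. LINC01522 rose by 1.66 without GTC365 replicate 2, and GDF15 by 3.18 without untreated replicate 2.

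The largest falls were in SIM1 (-3.10 ± 0.38), a neuronal transcription factor gene, KIF20A (-3.00 ± 0.15), PIMREG (-2.65 ± 0.21), the kinetochore gene NDC80 (-2.64 ± 0.14), the mitotic kinase gene PLK1 (-2.62 ± 0.17) and the helicase gene PIF1 (-2.61 ± 0.27). KIF20A (10112) lies on chromosome 5 at 138179112 to 138187723, and PLK1 (5347) on chromosome 16 at 23678889 to 23690367. Adjusted p-values ran from 8.06e-05 (KIF20A and NDC80) to 0.00166 (SIM1) in edgeR's quasi-likelihood test. SIM1 fell by 3.94 without GTC365 replicate 1.

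Among 40 tested genes of G2/M and mitosis, all 40 fell after GTC365, also when adjusted over the list alone, with a median log2 change of -2.24. TOP2A, the replication-associated topoisomerase, fell from 512 ± 12.8 to 127 ± 8.49 CPM, and TTK and KIF23 fell by 2.38 and 1.92. Of 40 genes of G1/S and DNA replication, 39 fell (40 when adjusted over the list alone), with a median of -1.70. These included GINS2 (-2.12 ± 0.10) and CDC45 (-2.07 ± 0.11) of the replicative helicase and the thymidine kinase gene TK1 (-2.04 ± 0.10). Homologous recombination and Fanconi genes fell in 32 of 36 cases (34 when adjusted over the list alone; median -1.30), among them FANCI (-1.93 ± 0.10), FANCD2 (-1.61 ± 0.09) and BRCA1 (-1.86 ± 0.10). The lists passed camera with a preset correlation at adjusted p-values of 1.67e-143, 4.54e-103 and 4.18e-44. All 3 gave adjusted p = 0.0858 in camera with an estimated correlation and adjusted p = 0.00419 in fry.

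Of 35 tested p53 target genes, 29 rose after GTC365 (30 when adjusted over the list alone) and none fell, with a median of 1.09 and a camera adjusted p of 5.28e-32 (adjusted p = 0.0858 with an estimated correlation). Alongside CDKN1A, the leading members were SPATA18 (2.20 ± 0.19), with a role in removing damaged mitochondria, and the stress-induced SESN2, whose adjusted p was 1.85e-04 in edgeR's quasi-likelihood test. BCL2-family apoptosis regulators rose in 5 of 16 cases (6 when adjusted over the list alone; median 0.21, adjusted p = 0.00795, and adjusted p = 0.227 with an estimated correlation). They included the pro-apoptotic BBC3 (1.75 ± 0.16), BAX (0.83 ± 0.11) and BMF (0.60 ± 0.11), while BCL2 itself measured 0.08 ± 0.26. BBC3 and BAX are also members of the p53 list, so these lists are not independent. BMF measured 0.51 to 0.68 over fits without each library in turn, and its call was lost without untreated replicate 1. Inflammatory and senescence-associated secreted factors rose in 4 of 19 cases (4 when adjusted over the list alone; median 0.65, adjusted p = 0.00296, and adjusted p = 0.227 with an estimated correlation). Those were led by the protease gene PLAU (1.83 ± 0.20), the cytokine gene LIF (2.30 ± 0.27) and VEGFA (1.11 ± 0.14). The fourth was GDF15, also a member of the p53 list.

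**Figure D2:**
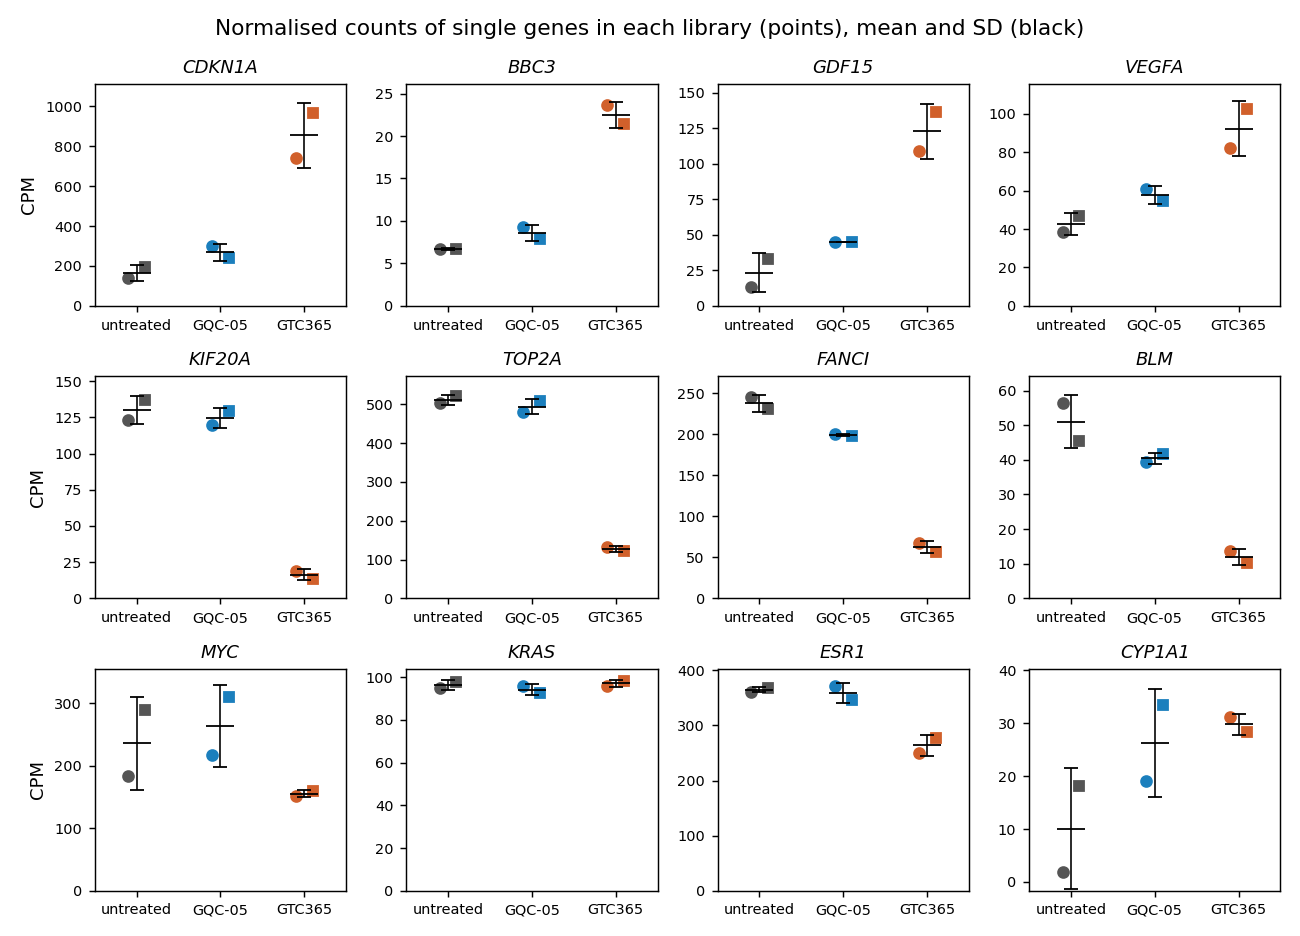
Normalised counts (CPM, linear axes) of 12 genes in each library, with circles for replicate 1, squares for replicate 2, and black lines for the mean and SD of the 2 libraries of a group. CDKN1A, BBC3, GDF15 and VEGFA lay higher and KIF20A, TOP2A, FANCI and BLM lower in both GTC365 libraries than in all others, and the SD of untreated CYP1A1 extends below 0.

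Proteins that unwind or bind G4 structures formed a list of 36 tested genes, of which 15 fell and none rose after GTC365 (18 fell when adjusted over the list alone; median -0.29). Camera gave an adjusted p of 4.03e-09 for this list, and adjusted p = 0.212 with an estimated correlation. The smallest p-values were those of BRIP1 (-1.49 ± 0.10) and BLM (-2.10 ± 0.17), helicases that are also members of the recombination list, and of the RNA-binding protein gene HNRNPA2B1 (-1.03 ± 0.08). The largest fall of the list was that of PIF1 (-2.61). Of 26 tested genes with G4 structures described in their promoters or 5′ untranslated regions, 7 rose and 2 fell (7 and 2 when adjusted over the list alone), with a median of 0.07 and a camera adjusted p of 0.220. The members with the smallest p were CCND1, the cyclin D1 gene, which rose by 1.05 ± 0.13, and PARP1, which fell by 0.82 ± 0.09. MYC, the best known of them, measured -0.60 ± 0.23, from 236 ± 74.3 to 155 ± 5.52 CPM, with an adjusted p of 0.105 in edgeR's quasi-likelihood test. MYC passed under some alternatives, among them DESeq2 (0.0369) and the fit without untreated replicate 1 (0.0327), and its adjusted p ran up to 0.442, without untreated replicate 2. KRAS measured 0.01 ± 0.08 and KIT -0.07 ± 0.48. KIT measured -0.99 without GTC365 replicate 2. TERT had 1 to 9 reads per library, too few to test.

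**Figure D3:**
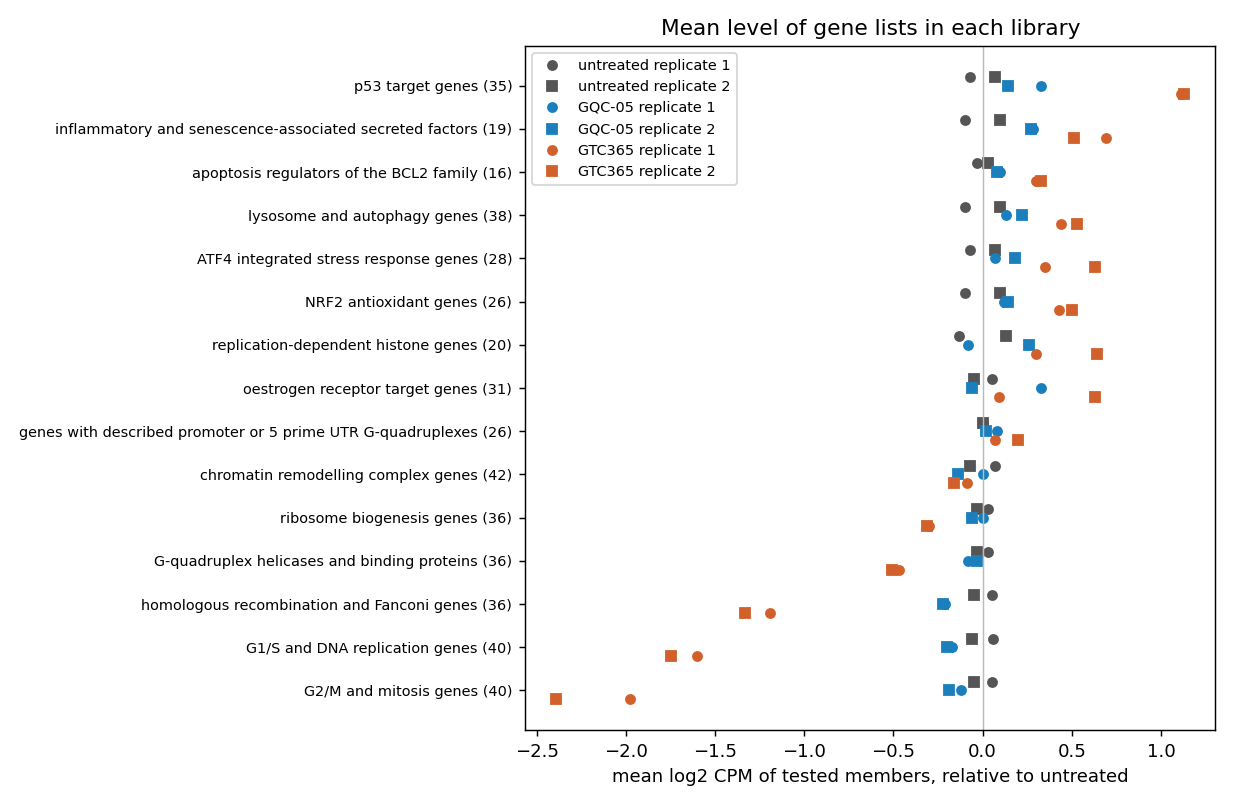
Mean log2 CPM of the tested members of 15 gene lists in each library, relative to the mean of the untreated libraries, with the number of tested members in brackets. Both GTC365 libraries lay above 1 for p53 target genes and below -1 for the recombination, G1/S and G2/M lists, while the GQC-05 libraries lay between -0.22 and 0.33 for these 4 lists.

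Stress and metabolic lists also moved after GTC365. Lysosome and autophagy genes rose in 21 of 38 cases, with 1 fall (29 and 1 when adjusted over the list alone; median 0.45), led by the lysosomal enzyme genes GNS (0.86 ± 0.11) and CTSA (0.67 ± 0.08) and the autophagy receptor gene SQSTM1 (0.86 ± 0.12). NRF2 antioxidant genes rose in 11 of 26 cases (11 when adjusted over the list alone; median 0.33), among them G6PD (1.15 ± 0.10) and TKT (0.75 ± 0.09) of the pentose phosphate pathway and the ferritin gene FTL (0.65 ± 0.12). ATF4 integrated stress response genes rose in 10 of 28 cases, with 1 fall (14 and 1 when adjusted over the list alone; median 0.38), led by DDIT4 (1.23 ± 0.09), SESN2 and ATF4 (0.42 ± 0.08). Camera adjusted p-values were 2.88e-09, 0.00108 and 3.35e-04. With an estimated correlation the lists gave adjusted p = 0.227, adjusted p = 0.227 and adjusted p = 0.372. SESN2 is also a member of the p53 list. The calls of ATF4 (without untreated replicate 1 or GTC365 replicate 2; 0.37 to 0.46 over the leave-outs) and FTL (without GTC365 replicate 1; 0.59 to 0.69) were lost when the libraries named were left out.

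Ribosome biogenesis genes fell in 15 of 36 cases (21 when adjusted over the list alone; median -0.30, adjusted p = 4.09e-05, and adjusted p = 0.321 with an estimated correlation). Among them were the nucleolar genes FBL (-0.75 ± 0.08), DKC1 (-0.59 ± 0.08) and NOP56 (-0.58 ± 0.08). Cytosolic ribosomal protein genes shifted slightly the other way (median 0.13, camera adjusted p = 0.00887, and adjusted p = 0.477 with an estimated correlation). Of 77, 7 rose (1 when adjusted over the list alone). That share was near that of all tested genes, of which 1190 of 13900 rose. RPS19 (0.61 ± 0.10), RPL28 (0.52 ± 0.11) and RPL13A (0.35 ± 0.08) led them, and reads of such genes can be shared with their pseudogenes. The list gave an adjusted p of 0.0524 without untreated replicate 1. RPL13A lost its call without any 1 untreated or GTC365 library (0.31 to 0.37), and RPL28 without untreated replicate 2 or GTC365 replicate 2 (0.39 to 0.64).

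Of 20 tested replication-dependent histone genes, 8 rose and 1, H3C2, fell after GTC365 (10 and 2 when adjusted over the list alone; median 0.55), in contrast to the G1/S list. The camera adjusted p was 0.00617, and adjusted p = 0.477 with an estimated correlation. H2BC5 (0.42 ± 0.08), H2BC21 (0.80 ± 0.16) and H4C8 (1.69 ± 0.34) led the rise, all lost their calls without untreated replicate 1 or GTC365 replicate 2 (lowest values 0.39, 0.62 and 1.11), and near-identical copies may share their reads. Aryl hydrocarbon receptor targets rose in 3 of 10 cases (4 when adjusted over the list alone; median 0.68, adjusted p = 0.0111, and adjusted p = 0.372 with an estimated correlation). These were UGT1A6 (1.71 ± 0.36), which shares exons with neighbouring UGT1A genes, the amino acid transporter gene SLC7A5 (1.45 ± 0.32) and TMEM45B (1.16 ± 0.29). All 3 calls were lost without untreated replicate 1 and without 1 GTC365 library, replicate 2 for SLC7A5, replicate 1 for UGT1A6 and either for TMEM45B (lowest values 0.89, 1.09 and 0.73). TMEM45B measured 1.77 without untreated replicate 2. CYP1A1, the classic target, measured 1.57 ± 0.70 (edgeR adjusted p = 0.163), with 27 and 256 reads in the untreated libraries. It measured 0.72 without untreated replicate 1 and 3.93 without untreated replicate 2, where it passed (adjusted p = 0.00149).

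Oestrogen receptor target genes, a programme on which MCF-7 growth depends, rose in 5 of 31 cases and fell in 1 (5 and 1 when adjusted over the list alone; median 0.32, adjusted p = 0.0227, and adjusted p = 0.678 with an estimated correlation). CCND1, FHL2 (0.80 ± 0.17) and RET (0.81 ± 0.20) were the leading members. The list's median was -0.01 without GTC365 replicate 2 (adjusted p = 0.433) and 0.18 without untreated replicate 2 (adjusted p = 0.0756). FHL2 (0.64 to 0.98 over the leave-outs) lost its call without untreated replicate 1 or either GTC365 library, and RET (0.50 to 1.05) without either untreated library or GTC365 replicate 2. ESR1, the receptor gene itself, fell by 0.47 ± 0.09, from 365 ± 4.58 to 264 ± 18.8 CPM, and lost its call without GTC365 replicate 1 (-0.55 to -0.40). Mesenchymal genes rose in 2 of 16 cases (1 when adjusted over the list alone; median 0.56, adjusted p = 0.0240, and adjusted p = 0.227 with an estimated correlation). The changed members were ACTA2 and CDH11 (0.80 ± 0.23), and COL5A1 measured 0.84 ± 0.28. The mesenchymal list lost its call without untreated replicate 1, GQC-05 replicate 2 or GTC365 replicate 1 (median 0.34 to 0.52 over the leave-outs). It also lost its call with no filter beyond 1 read. CDH11 lost its call without any 1 library (0.68 to 0.90).

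Other lists did not pass camera after GTC365, with adjusted p-values from 0.0758 (non-coding RNAs) to 0.939 (fatty acid synthesis). Some passed under alternatives. The adjusted p was 0.00301 for non-coding RNAs and 0.00546 for cholesterol genes without GTC365 replicate 1, 6.72e-05 for immediate early and 0.0496 for chromatin remodelling genes without untreated replicate 2, and 0.0251 for basal markers without GTC365 replicate 2. With no filter beyond 1 read it was 0.0247 for cholesterol and 0.0176 for chromatin remodelling genes, and with fry 0.0386 for telomere genes. Cholesterol synthesis genes fell in 6 of 27 cases (7 when adjusted over the list alone), led by ACAT2 (-1.07 ± 0.11) and TMEM97 (-0.66 ± 0.09). Chromatin remodelling genes, named in the study's title, fell in 5 of 42 cases (2 when adjusted over the list alone), led by the helicase gene HELLS (-1.46 ± 0.17) and ACTL6A (-0.44 ± 0.08), the latter lost without untreated replicate 1 or GTC365 replicate 2 (-0.45 to -0.42). The adjusted p of that list was 0.204, with a median of -0.10. Its share of falls was near that of all tested genes, of which 1439 of 13900 fell. Of 39 histone modifier genes 3 rose and 8 fell (4 and 9 when adjusted over the list alone), with the demethylase gene KDM6B at 0.92 ± 0.09 and the Polycomb gene EED at -0.82 ± 0.09. Telomere genes rose in 2 and fell in 5 of 16 cases (3 and 6 when adjusted over the list alone), with DKC1 and WRAP53 (-1.02 ± 0.14), which is antisense to TP53 and may hold its reads. Luminal identity genes rose in 3 and fell in 2 of 25 cases (3 and 2 when adjusted over the list alone), with KRT19 (0.54 ± 0.08) and ESR1 leading. Hypoxia and glycolysis genes rose in 2 and fell in 4 of 26 cases (2 and 4 when adjusted over the list alone), led by VEGFA and ENO1 (-0.45 ± 0.08), which lost its call without GTC365 replicate 2 (-0.50 to -0.42).

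Smaller counts were found in the remaining lists after GTC365. Among all 13900 tested genes 1190 rose and 1439 fell. Counts in the lists tested here were of the order of those shares or below, so they do not mark a list as responding. Fatty acid synthesis genes rose in 2 and fell in 2 of 16 cases (2 and 2 when adjusted over the list alone), led by ELOVL6 (-0.98 ± 0.15) and GPAM (-0.54 ± 0.12). Genes of the unfolded protein response fell in 2 of 24 cases (2 when adjusted over the list alone), HSP90B1 (-0.53 ± 0.07) and CRELD2 (-0.52 ± 0.12). Heat shock genes fell in 3 of 23 cases (2 rose and 5 fell when adjusted over the list alone), led by HSPD1 (-0.46 ± 0.09) and AHSA1 (-0.37 ± 0.09). Of 32 interferon-stimulated genes PARP9 rose by 0.48 ± 0.13 and OAS3 fell by 0.48 ± 0.13 (0 and 0 when adjusted over the list alone). Of 22 immediate early genes FOSL1 (2.02 ± 0.46) and KLF4 (0.92 ± 0.25) rose (0 when adjusted over the list alone). CDH3 (0.42 ± 0.10) rose among 15 basal and myoepithelial markers (1 when adjusted over the list alone), and RN7SK (2.07 ± 0.43), which has many genomic copies, among 7 abundant non-coding RNAs (2 when adjusted over the list alone). Of the haematopoietic markers 2 were expressed, too few for a list test, and CORO1A rose by 0.53 ± 0.09 (1 when adjusted over the list alone). No gene of the mitochondrially encoded list was matched in the count table. Many of these calls were lost when a library was left out. Without untreated replicate 1 or GTC365 replicate 1, and for some genes others too, those of GPAM (-0.63 to -0.44 over the leave-outs), CRELD2 (-0.57 to -0.48), AHSA1 (-0.43 to -0.32), PARP9 (0.32 to 0.61), FOSL1 (1.49 to 2.87), CDH3 (0.29 to 0.52) and RN7SK (1.58 to 2.42) were lost. Without GTC365 replicate 2 those of HSPD1 (-0.54 to -0.38), OAS3 (-0.63 to -0.36) and KLF4 (0.52 to 1.47) were lost. FOSL1 measured 2.87 without untreated replicate 2.

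No gene changed after GQC-05 against untreated cells. Of 13900 genes, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the smallest adjusted p being 0.998, and 525 had an unadjusted p under 0.05, against 695 expected with no change, in a fit that takes no account of replicate numbers. This count depended on single libraries, with 204 without untreated replicate 1, 243 without GQC-05 replicate 1 and 1026 without untreated replicate 2 (smallest adjusted p = 0.0680). limma-voom called 0 genes (537 unadjusted), and DESeq2 called 1 (274 unadjusted), FHL2, a LIM-domain protein gene, at an adjusted p of 0.00768. FHL2 (2274, chromosome 2, 105357712 to 105438529) measured 7.48 ± 1.24 CPM untreated and was higher by 1.19 ± 0.16 with GQC-05. Other genes with the smallest p were the focal adhesion gene ZYX (0.46 ± 0.09) and the sodium channel subunit gene SCN1B (0.65 ± 0.13) on the higher side, and LRRCC1 (-0.55 ± 0.12), RORC (-1.71 ± 0.44) and TEX14 (-0.65 ± 0.17) on the lower. Among the genes fixed for naming, CDKN1A measured 0.70 ± 0.20, VEGFA 0.43 ± 0.14, MYC 0.16 ± 0.23, KRAS -0.03 ± 0.08, BCL2 -0.13 ± 0.26, KIT 0.00 ± 0.48, ESR1 -0.02 ± 0.09 and CYP1A1 1.38 ± 0.71. CYP1A1 measured 0.53 without untreated replicate 1 and 3.75 without untreated replicate 2. The median SE was 0.144 on the log2 scale, so changes under about 2-fold were often below what the test could call.

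Lists of genes shifted slightly with GQC-05 without any called member, over all genes or, FHL2 apart, when adjusted over the list alone. Of 30 lists tested, 12 passed camera with the preset correlation. Proteins acting on G4 structures (median -0.03, adjusted p = 0.0661) and genes with described promoter G4 structures (0.05, 0.188) were among the 18 that did not. The former passed with library size alone (0.0350), in a fit of only the groups compared (0.0491) and without untreated replicate 2 (0.0368). Median log2 changes were 0.17 for p53 target genes (30 of 35 positive, adjusted p = 6.25e-10), -0.18 for G1/S (38 of 40 negative, 4.44e-13), -0.16 for G2/M (39 of 40 negative, 6.07e-08) and -0.21 for recombination genes (34 of 36 negative, 9.26e-13). Lysosome genes had a median of 0.16 (36 of 38 positive, 1.07e-09), secreted factors 0.19 (4.35e-04), aryl hydrocarbon receptor targets 0.40 (10 of 10 positive, 3.96e-05), NRF2 genes 0.11 (0.00642), ATF4 genes 0.10 (0.0390), oestrogen receptor targets 0.10 (0.00526), luminal genes 0.10 (0.0114) and cholesterol genes 0.06 (0.0343). With an estimated correlation none of the 12 passed, from adjusted p = 0.332 to adjusted p = 0.699 with an estimated correlation, and fry gave 0.478 to 0.721. Members with the smallest p were PHLDA3 (0.55 ± 0.12), DDIT4 (0.35 ± 0.09), CTSA (0.36 ± 0.08), PRIM1 (-0.32 ± 0.10), TTK (-0.29 ± 0.10) and RAD51C (-0.25 ± 0.08). Without untreated replicate 1 the calls of the aryl hydrocarbon receptor (0.156), NRF2 (0.309) and ATF4 (0.290) lists were lost. Without untreated replicate 2 those of cholesterol (0.428) and oestrogen receptor genes (0.204) were lost, without GQC-05 replicate 2 that of ATF4 genes (0.232), and without GQC-05 replicate 1 those of luminal (0.287), cholesterol (0.263) and oestrogen receptor genes (0.300, median -0.05).

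The direct comparison of the treatments, whose doses differ, gave lower cell division genes and higher p53 targets with GTC365 than with GQC-05. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1484 genes differed, 522 higher and 962 lower with GTC365. CDKN1A stood at 269 ± 43.0 CPM with GQC-05 and 855 ± 162 with GTC365 (1.67 ± 0.20), and TOP2A at 494 ± 19.5 and 127 ± 8.49 CPM. The largest positive differences were in the lipid transporter gene ABCA12 (2.33 ± 0.21), LINC01522 (2.27 ± 0.44), TNFRSF10C (1.99 ± 0.25), CDSN (1.96 ± 0.38) and the receptor gene EDA2R (1.84 ± 0.20). The largest negative ones were in KIF20A (-2.93 ± 0.15), PIF1 (-2.55 ± 0.27), PLK1 (-2.48 ± 0.17), PIMREG (-2.46 ± 0.21) and DLGAP5 (-2.43 ± 0.18), with edgeR adjusted p-values from 1.57e-04 (KIF20A) to 0.00126 (PIF1). The count was 564 without GQC-05 replicate 1, 545 without GQC-05 replicate 2, 945 without GTC365 replicate 1 and 440 without GTC365 replicate 2. LINC01522 lost its call without either GQC-05 library and measured 1.36 without GTC365 replicate 2, and CDSN lost its call without those libraries (1.23 to 2.43 over the leave-outs).

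By list, 40 of 40 G2/M genes, 39 of 40 G1/S genes and 29 of 36 recombination genes were lower with GTC365 than with GQC-05 (40, 40 and 34 when adjusted over the list alone), with medians of -2.03, -1.46 and -1.08. CDK1 (-1.85 ± 0.10), GINS2 (-1.91 ± 0.10) and FANCI (-1.67 ± 0.10) were among them. Of 35 p53 targets 26 were higher (30 when adjusted over the list alone; median 0.81), among them SPATA18 (1.73 ± 0.18) and CCNG1 (0.98 ± 0.11). The 4 lists passed camera, and each gave adjusted p = 0.0885 with an estimated correlation. Proteins acting on G4 structures were lower in 14 of 36 cases (16 when adjusted over the list alone; median -0.26, camera adjusted p = 1.68e-09, and adjusted p = 0.202 with an estimated correlation), with BLM at -1.76 ± 0.17. Cholesterol synthesis genes were lower in 6 of 27 cases (6 when adjusted over the list alone; median -0.18, adjusted p = 0.00726, and adjusted p = 0.636 with an estimated correlation), led by EBP (76.2 ± 8.19 CPM with GQC-05 and 38.1 ± 8.29 with GTC365), ACAT2 (-0.97 ± 0.11) and TMEM97 (-0.77 ± 0.09). That list's adjusted p was 0.149 without GTC365 replicate 2. Lysosome, NRF2, ATF4, BCL2-family, ribosomal protein, histone, secreted factor and mesenchymal lists were higher and the ribosome biogenesis list lower by camera (adjusted p from 1.40e-05 to 0.0383). With an estimated correlation these ran from adjusted p = 0.335 to adjusted p = 0.489. Leaders with calls kept in every leave-out fit included G6PD (0.92 ± 0.10), DDIT4 (0.88 ± 0.09), BBC3 (1.39 ± 0.15) and FBL (-0.67 ± 0.08). The secreted factor and mesenchymal lists lost their calls without GQC-05 replicate 1, GQC-05 replicate 2 or GTC365 replicate 1. Their medians over the leave-outs ran from -0.01 to 0.15 and from 0.07 to 0.46. Both lists also lost their calls with no filter beyond 1 read. The histone list lost its call without GQC-05 replicate 1 (median 0.42 to 0.73 over the leave-outs).

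No gene changed in the same direction with both ligands, because none changed with GQC-05. Fold changes of all 13900 genes correlated across genes, which are not independent replicates, with Pearson's r = 0.50 and Spearman's rho = 0.52. In 20 simulations with all 6 libraries redrawn unchanged, the shared untreated group gave 0.495 (0.468 to 0.520) and 0.456 (0.444 to 0.471). The share of genes with the same sign was 69% against 66.5% simulated (65.76 to 67.16). The simulations left out the response to GTC365, which widens the spread of its fold changes. They also drew each library independently, whereas differences between replicates correlated at 0.63 across genes between untreated and GQC-05. Their r therefore cannot show how much of the observed 0.50 came from the shared untreated libraries. The covariance, which is not divided by that spread, was 0.0740 against 0.0385 simulated (0.03555 to 0.04238), a difference of 0.0355. Taken instead from the difference between the 2 untreated libraries, the shared part was 0.0370, which left 0.0370. Part of either remainder may still come from the shared untreated libraries, which could not be split into groups of 2. With a separate untreated library for each ligand, a comparison added after the data were examined, the mean r over the 8 ways was 0.16. The mean covariance over these ways was 0.0313. Each way used single libraries, whose greater noise also lowers r.

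The longest genes shifted slightly upward after GTC365. Across 12508 protein-coding genes, gene span and log2 change had a Spearman correlation of 0.06 for GTC365 against untreated, 0.07 for GTC365 against GQC-05 and -0.02 for GQC-05 against untreated. In the longest of 5 classes, with a median span of 165 kb, 272 genes rose and 130 fell after GTC365 (median log2 change 0.09). In the shortest, with a median span of 5.39 kb, 214 rose and 273 fell (median 0.01). The classes between them, from shorter to longer, had medians of -0.02, -0.03 and -0.01, so the shift was not graded with length. Without GTC365 replicate 1 the first correlation was 0.02.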

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

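Tests of gene lists without a count filter, with only the groups compared, in a robust fit and without abundant non-coding RNAs, and the separate untreated library for each ligand, were chosen after the results were seen. GQC-05 changed 0 genes under every alternative except DESeq2, which called 1. With library size alone, GTC365 raised 1075 and lowered 1558 genes. Counts of changed genes over fits without each library ran from 930 to 2132 for GTC365 against untreated and from 440 to 1381 for GTC365 against GQC-05. The lone library and the fewer residual degrees of freedom lower such counts by construction, and shared genes kept their direction. Named genes lost 72 calls, in 27 of 80 called genes, in the former and 115, in 35 of 70, in the latter. Under other scalings, filters and tools, calls were lost in at most 4 named genes of a comparison per kind of alternative, and in 7 under fits of only the groups compared, a robust fit or one without abundant non-coding RNAs.

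With an estimated correlation 12, 16 and 15 lists lost their call for GQC-05 against untreated, GTC365 against untreated and the direct comparison, and with fry 12, 4 and 8. The 4 lost with fry after GTC365 were the ATF4 (fry adjusted p = 0.0589), aryl hydrocarbon receptor (0.0960), histone (0.108) and oestrogen receptor lists (0.313). Simulated lists with a true shift also lost their call with an estimated correlation, but their genes were drawn independently of each other. In real lists after GTC365 the estimated correlation was 0.574 for G2/M genes, 0.153 for p53 targets and -0.035 for BCL2-family genes. The simulation therefore cannot tell whether real lists lost their calls for lack of power. Over fits without each library, the medians of 2 GQC-05 lists reversed where the list had a call with or without the library, oestrogen receptor targets (-0.05 to 0.30, negative without GQC-05 replicate 1) and immediate early genes (-0.29 to 0.76, at -0.26 without untreated replicate 1 and -0.29 without GQC-05 replicate 2). Medians of several lists without a call changed sign too, such as histone genes (-0.09 to 0.30), and uncalled lists gained a call 20, 5 and 5 times over these fits of the 3 comparisons, in the order above. The cause was not tested. The correlation between the ligands' fold changes ran from 0.33 to 0.68 and was 0.16 with separate untreated libraries, which removes shared chance values but also sets single libraries against each other, whose noise lowers it. Correlations with gene span ran from -0.07 to 0.05 for GQC-05 (0.01 without untreated replicate 1), 0.02 to 0.09 for GTC365 and 0.03 to 0.11 for the direct comparison. With exonic length they were 0.10 and 0.13 for the last pair, and 0.09 and 0.11 among genes above the median CPM. The cause was not tested. The promoter motif search and its alternatives were not run. A depth of 12387664 to 14064949 counts per library left TERT untested.

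Replicate numbers were checked as possible pairs. The difference between replicates 2 and 1 correlated across 10071 genes at 0.63 between untreated and GQC-05, 0.14 between untreated and GTC365, and 0.20 between the ligands, with only 2 pairs per comparison. With the number as a block, 0 genes changed for GQC-05 (1051 at an unadjusted p under 0.05, above the 695 expected with no change, against 525 without the block), 3991 for GTC365 against untreated and 2671 for the direct comparison, including all 2629 and 1484 genes called without the block. For GTC365 against untreated, the block also gave calls to MYC (-0.57, adjusted p = 0.0162), CYP1A1 (1.82, 0.0483) and the non-coding RNA list (0.0423), and for GQC-05 to the list of proteins acting on G4 structures (0.0493), among others.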

Other observations

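All tests in this part were chosen after the data were examined. Those of untreated replicate 1, of the replicate numbers, of the histone genes and of the total share of changed motif genes were chosen only after the result they measure was seen. For the tests of shared untreated libraries, of a weaker GTC365-like response, of members shared with the recombination list and of the first-exon motif, predictions were written before their own result was seen.

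Enzymes that write or erase histone marks moved apart within their list after GTC365. The names here were chosen after their values were seen. All 3 core genes of Polycomb complex 2 fell, EZH2 (adjusted p = 0.00124), EED by 0.82 ± 0.09 and SUZ12 by 0.38 ± 0.09, as did the H3K9 methyltransferase genes SUV39H1 (-1.29 ± 0.19) and SUV39H2 (-0.93 ± 0.13) and NSD2 (-0.85 ± 0.11). The demethylase genes KDM6B (0.92 ± 0.09), KDM5B (0.77 ± 0.09) and KDM4A (0.49 ± 0.08) rose, while KDM1A (-0.38 ± 0.08) and HDAC1 (-0.43 ± 0.10) fell. Adjusted p-values in edgeR's quasi-likelihood test ran from 6.64e-04 (KDM6B) to 0.0260 (SUZ12).

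Telomere genes also split. After GTC365 the shelterin genes TERF1 (-0.46 ± 0.10) and ACD (-0.61 ± 0.15) fell and TINF2 (0.45 ± 0.09) rose, as did STN1 (0.63 ± 0.15) of the CST complex. TERF2 measured -0.02 ± 0.14 and POT1 -0.18 ± 0.13. GAR1 (-0.45 ± 0.11) fell with DKC1 (-0.59 ± 0.08), both of the box H/ACA particle. Names were again chosen after values were seen, with edgeR adjusted p-values up to 0.0279 for the called genes.

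The small list shifts in GQC-05 libraries ran in the direction of GTC365, except cholesterol synthesis (0.06 against -0.13). Without untreated replicate 1, 9 of the 12 lists that passed with the preset correlation kept their call. These lists were picked from the same 6 libraries. None of the 12 passed camera with an estimated correlation (adjusted p from 0.332 to 0.699) or fry. The kept calls therefore cannot exclude untreated replicate 1 as a source of the shifts. With a separate untreated library for each ligand, 7 of 8 covariances of the fold changes were above 0 (-0.0101 to 0.0585), and the mean slope of GQC-05 on GTC365 changes was 0.0930. The negative one mixed replicate numbers within each ligand, and both ways that kept them together were above 0 (0.0485 and 0.0397). These 2 ways rest on the same 6 libraries and were no part of the prediction, which asked for all 8 above 0. They therefore decide nothing. Chance in the shared untreated libraries and a weak GTC365-like response may both contribute. They cannot be told apart with 2 libraries per group and no gene called.

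Replicate numbers also separated libraries within groups. RN7SL1 and RN7SL2, the RNA of the signal recognition particle, were at least 8.22 times higher in replicate 2 of each group, and the mean of immediate early genes was higher by 0.33 to 1.11 (log2). A preparation batch shared by number may account for these, although no label names one. It would not account for oestrogen receptor targets, which were lower in replicate 2 of the untreated and GQC-05 groups (-0.11 and -0.38) and higher by 0.53 in that of GTC365. GREB1 stood at 634 and 287 CPM in the untreated libraries and at 555 and 916 CPM with GTC365. No biological explanation of the replicate differences was tested.

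After GTC365 8 of 20 histone genes rose and 1 fell while S-phase genes fell, although the histone list lost its call with an estimated correlation (adjusted p = 0.477) and with fry (0.108). The list median was at least 0.40 without either GTC365 library, so a single one does not account for that median. Calls of the leading members did depend on single libraries, as given above. The list mean was also higher in replicate 2 of each group, by 0.27 (untreated), 0.34 (GQC-05) and 0.35 (GTC365). Relative to untreated it was 0.30 and 0.64 in the GTC365 libraries, and -0.08 and 0.26 in those of GQC-05. Replication-dependent histone transcripts mostly lack a poly(A) tail, and 5 other abundant RNAs without a tail reached at most 4.84 CPM in any library, against a median of 26.7 to 27.8 CPM over tested genes. RN7SL1 and RN7SL2 together stood at 39.8 to 51.6 CPM in the replicate 2 libraries, above that median. In the replicate 1 libraries they stood at only 3.46 to 5.19 CPM. The named kit does not select for a tail, and the counting of multi-copy RNAs may also lower values. RN7SK also rose after GTC365 (2.07 ± 0.43), and all 7 non-coding RNAs tested were positive (median 0.94), although that list did not pass (adjusted p = 0.0758). A larger share of histone transcripts with a tail, a better yield of RNAs without a tail in the GTC365 libraries and a true rise of histone transcripts may each contribute and stay open, and H2BC21 and H2BC12 alone held 42.8% and 22.5% of the list's reads.

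As a hypothesis, G4-binding proteins may have fallen after GTC365 only because some also belong to the recombination list. Without BLM and BRIP1 the remaining 34 genes had a median of -0.26, with 13 falls and a camera p of 2.87e-07, so these members do not account for the shift found with the preset correlation. The full list gave adjusted p = 0.212 with an estimated correlation. Others of the 34, such as DNA2 (-1.44) and DDX11 (-0.99), also act in DNA replication or repair.

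A second hypothesis was that genes with a G4 motif at the start of their first exon may have changed more often. Of 12491 genes 2754 had one. In total they did not change more often after GTC365 (19.9% against 20.4% of the others). With GC content, searched length and expression in the model, the odds ratio of a change was 1.01 (95% interval 0.89 to 1.13). The directions differed, since 11% of these rose against 8.5% of the others. The odds ratio of a rise was 1.23 (95% interval 1.06 to 1.44) with GC content, searched length and expression in the model. The interval included 1 without untreated replicate 2 (0.96 to 1.36) and without GTC365 replicate 1 (0.98 to 1.47). Falls were less frequent with the motif (8.9% against 11.8%). Their odds ratio in the same model was 0.81 (0.69 to 0.95), with an interval reaching 1.04 without GTC365 replicate 2. All these intervals treat genes as independent. The motif is a sequence pattern in part of the transcript, and no G4 structure was measured here.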
